A study of Homo sapiens with 22 samples.

How the data were processed

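RNA levels were measured in 3 human liver cancer cell lines, Huh7, HepG2 and Hep3B, each transfected for 48 h with 15 nM of an siRNA against COP1 or of a negative control siRNA. COP1 is a RING-type E3 ubiquitin ligase. The series holds 22 arrays in 6 groups, with 3 arrays per siRNA in Huh7 and 4 per siRNA in HepG2 and in Hep3B. Per the labels, total RNA was extracted with Trizol, amplified to biotin-labelled cRNA and hybridized to Illumina HumanRef-8 v3 bead arrays, whose probes each target 1 transcript region. The design text names a single COP1 siRNA, and its sequence was not used here. The labels do not say whether replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

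The values used are the deposited bead intensity of each probe on a linear scale, which the authors had background-subtracted and quantile-normalized between the 22 arrays with GenomeStudio 2009.1. The background subtraction was read from the values, of which 23.7% lay below 0, and the normalization from the value distribution, which all arrays shared. The methods of both steps are not given in the sources used here. A second table of values not normalized between arrays, with detection p-values, names its columns in a way that matches no sample label. Its 44 per-sample columns were not used here.

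Each array was background-corrected with the normexp model of limma 3.58.1 under R 4.3.3, with an offset of 50, then log2-transformed and quantile-normalized between arrays. Fold changes are therefore on the scale of log2 of the normexp intensity plus 50, which understates the changes of dim genes. Because the planned filter needed detection p-values that could not be assigned to samples, another filter was chosen after the tables had been read and before any test. A probe counted as above background on an array when its intensity exceeded 21.8, the 0.98 quantile of the sizes of the values below 0. Probes above background on at least 3 arrays were kept, 16563 of 24526. Of the 24526 probes, 21834 carried a gene symbol and 2692 carried none. Each gene was represented by its probe with the highest mean level, and probes with no symbol stayed separate, which gave 13870 features, 12257 of them named. These are called genes here. Where a gene lies was read from the RefSeq annotation of GRCh38.p14, to which 21813 probes were matched by gene identifier. Between 12618 and 12642 probes were above background per array, a range that the shared distribution of values fixes. The number of arrays limits the precision of each value.

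One linear model with 6 group means was fitted to all 22 arrays with limma's lmFit and eBayes, with 16 residual degrees of freedom and a prior of 9.41. The contrasts were COP1 siRNA against control siRNA in each line, the average of these over the 3 lines, each difference between lines, and an F test of any difference between the 3 lines. P-values were adjusted by the method of Benjamini and Hochberg over all 13870 genes within each contrast, and genes with an adjusted p under 0.05 count as changed. A gene changed in the same direction in all 3 lines counts as shared. All p-values are two-sided.

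Before the data were examined, 17 gene lists were fixed. They cover growth arrest and DNA damage targets, COP1 and related ubiquitin ligases, G1/S and DNA replication, G2/M and mitosis, apoptosis regulators, AP-1 and immediate early genes, PEA3 ETS factors and MAPK output, hepatocyte markers, cholesterol synthesis and uptake, fatty acid metabolism, the unfolded protein and integrated stress response, the interferon response, NF-kB and acute phase genes, cytoskeleton, matrix and EMT genes, hypoxia and glycolysis, markers of fibroblasts, endothelium and leukocytes, and housekeeping controls. Each list was tested against the other genes with limma's camera with a preset correlation of 0.01, again with an estimated correlation, and by itself with fry. List p-values were adjusted over the 17 lists and the 3 lines together, over the 17 lists for the average, and over the lists and the differences between lines together. The contrasts, tests and alternatives and the rule for naming genes were also fixed before the data were examined.

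The genes named are COP1, and in each line the 10 largest rises and 10 largest falls among changed genes whose COP1 siRNA arrays all lay on the same side of all control arrays. They are further the 15 rises and 15 falls with the largest smallest change among shared genes, the 10 genes with the smallest p in the F test, and up to 4 changed members per list and line with the smallest adjusted p. Which of these list members are named was chosen after their values were seen. One gene that the rule names is not reported here.

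The method was tested on simulated data with the means and spreads of these arrays, in which 200 genes per line were raised or lowered by 0.5, 1 or 2 on the log2 scale. With the same spread on all arrays, 33.8%, 92.4% and 98.5% of these were recovered in Huh7, 35.3%, 98.5% and 100% in HepG2, and 41.2%, 93.9% and 100% in Hep3B. False calls made up 5.1%, 3.1% and 5.5% of all calls in Huh7, HepG2 and Hep3B. When each simulated array kept its own spread, 239 false calls were made in Huh7, 61.6% of its calls, against 3 in HepG2 and 2 in Hep3B.

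The alternatives covered the background step, the normalization, the filter, the choice of probe, the fit, the threshold, the list test and leaving out each array in turn. A normexp offset of 16, a floor at the background threshold with no normexp, and a list test of differences between lines on genes above background on every array of at least 1 group in both lines were added after seeing the data. Ranges of a list's adjusted p leave out fry, which tests a list against no change. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.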

Results

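RNA was compared between cells given COP1 siRNA and cells given a negative control siRNA in the liver cancer cell lines Huh7, HepG2 and Hep3B. Huh7 had 3 arrays per siRNA, and HepG2 and Hep3B had 4 each. The median probe intensity lay between 24.3 and 24.5 on all 22 arrays, and 13870 genes were tested. Replicates deviated from their group mean by a root mean square of 0.12 to 0.27 on the log2 scale, apart from replicate 3 of the Huh7 COP1 siRNA group, which deviated by 0.42. The first principal component held 54.9% of the variance and the second 31.5%, and on these the 3 lines lay apart from each other.

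The first question was how far COP1 RNA had fallen. COP1 (probe ILMN_1661002; chromosome 1, 175944831 to 176207286 in GRCh38.p14) fell in each line and was lower on every COP1 siRNA array than on every control array of the same line. Its log2 fold change was -2.40 ± 0.12 (SE, n = 3 and 3) in Huh7, -1.78 ± 0.11 (n = 4 and 4) in HepG2 and -2.05 ± 0.11 (n = 4 and 4) in Hep3B. The limma adjusted p was 3.0e-13, 4.0e-12 and 2.1e-12 in these lines. Every SE and adjusted p of a gene given here rests on 1 spread shared by all 22 arrays. With each line fitted alone, the median residual SD was 0.23 in Huh7, 0.16 in HepG2 and 0.14 in Hep3B. The SEs and adjusted p of Huh7 genes thus tend to be too small. For COP1 in Huh7 fitted alone, the limma adjusted p was 0.00038. Mean intensity was 279 after COP1 siRNA and 1801 after control siRNA in Huh7, 410 and 1586 in HepG2, and 513 and 2356 in Hep3B. COP1 siRNA samples thus held 15.5%, 25.8% and 21.8% of the control intensity in Huh7, HepG2 and Hep3B. A second COP1 probe fell by 2.07, 1.89 and 1.98, and the third was not above background on any array. The fall was larger in Huh7 than in HepG2 on the main probe (limma adjusted p = 0.0063 for the difference), while on the second probe the difference of 0.18 ± 0.15 did not pass (adjusted p = 0.40).

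**Figure D1:**
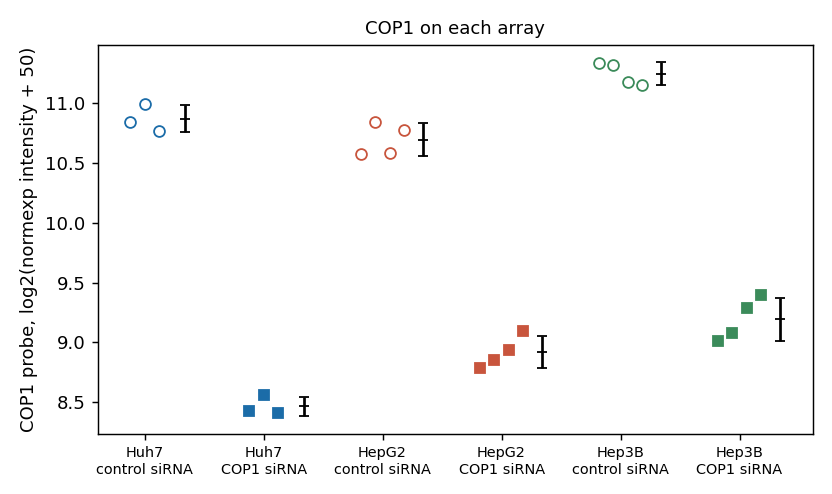
COP1 level on each of the 22 arrays, as log2 of the normexp intensity plus 50, by cell line and siRNA; each symbol is 1 array, and the bars show the mean and SD of the group. In each line all COP1 siRNA arrays lie below all control arrays, with a log2 fold change of -2.40 in Huh7, -1.78 in HepG2 and -2.05 in Hep3B.

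In Huh7, the hepatocyte marker list and the unfolded protein and integrated stress response list were lower after COP1 siRNA. The interferon response list and the cytokine gene CXCL8 were higher. The largest rise among named genes was that of GBP1, an interferon-induced GTPase, with a log2 fold change of 3.32 ± 0.17 (adjusted p = 1.9e-13). ANXA1, a phospholipid-binding protein, rose by 2.48 ± 0.20, the actin-binding protein gene TAGLN by 2.25 ± 0.22 and CXCL8 by 2.15 ± 0.16. F3, tissue factor, was at least 3.94-fold higher, its control arrays lying at background. The secreted glycoprotein gene STC2 fell by 2.98 ± 0.13 (adjusted p = 2.9e-14), INHBE, an inhibin subunit, by 2.85 ± 0.17, and CANX, the endoplasmic reticulum chaperone calnexin, fell by 2.57 ± 0.14. All of these were on one side of the controls on 3 of 3 arrays, which the rule for naming them required.

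Of 26 hepatocyte markers tested, 14 fell in Huh7 and 12 did not pass the test, and 16 fell adjusted over the list alone. The list's mean log2 fold change was -0.77 (camera adjusted p = 2.8e-07; adjusted p = 0.00092 with an estimated correlation). The hepatocyte transcription factor genes CEBPA and FOXA3 fell by 2.26 ± 0.16 and 2.25 ± 0.19, and the asialoglycoprotein receptor gene ASGR1 by 1.71 ± 0.16. Without replicate 3 of the COP1 siRNA group, which stood apart from the other arrays, the list's mean was -0.69. Of 26 unfolded protein and integrated stress response genes, 11 fell and 3 rose, or 13 and 3 adjusted over the list alone (mean -0.42; camera adjusted p = 0.0036; adjusted p = 0.018 with an estimated correlation). PHGDH of serine synthesis fell by 1.65 ± 0.14, the asparagine synthetase gene ASNS by 1.28 ± 0.14 and the pseudokinase gene TRIB3 by 1.35 ± 0.11, while the chaperone gene HSP90B1 rose by 0.61 ± 0.17.

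Of 24 interferon response genes, 10 rose and 14 did not pass, and 10 rose and 2 fell adjusted over the list alone (mean 0.35; camera adjusted p = 0.011; adjusted p = 0.04 with an estimated correlation). MX1, an antiviral GTPase, rose by 0.99 ± 0.15 and the RNA sensor gene IFIH1 by 1.40 ± 0.20. The list's call was lost without COP1 siRNA replicate 1 (adjusted p = 0.078) and with no background correction (adjusted p = 0.055), and its camera adjusted p lay between 0.00058 and 0.078 over all alternatives. Of 16 PEA3 ETS factor and MAPK output genes, 7 fell and 1 rose, or 7 and 2 adjusted over the list alone (mean -0.43; camera adjusted p = 0.0069; adjusted p = 0.077 with an estimated correlation). ETV4, a PEA3 family transcription factor, fell by 2.37 ± 0.12. Of 27 fatty acid metabolism genes, 10 fell and 2 rose, and the counts were the same adjusted over the list alone (mean -0.29; camera adjusted p = 0.012; adjusted p = 0.30 with an estimated correlation). The desaturase gene FADS1 fell by 1.73 ± 0.14 and the fatty acid synthase gene FASN by 1.16 ± 0.12, and the list's call was lost without COP1 siRNA replicate 1 (adjusted p = 0.085) or replicate 2 (adjusted p = 0.075), with a camera range of 0.00011 to 0.30 over all alternatives.

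Of 25 cytoskeleton, matrix and EMT genes, 11 rose and 1 fell in Huh7, or 13 and 1 adjusted over the list alone (mean 0.44; camera adjusted p = 0.0053; adjusted p = 0.25 with an estimated correlation). CDH2, N-cadherin, rose by 1.33 ± 0.15. Without the COP1 siRNA replicate that stood apart, replicate 3, the list's call was lost (adjusted p = 0.059, with a camera range of 0.00084 to 0.25 over all alternatives). Of 30 G2/M and mitosis genes, 11 rose and 3 fell, or 13 and 3 adjusted over the list alone (mean 0.31; camera adjusted p = 0.033; adjusted p = 0.37 with an estimated correlation). The mitotic kinesin gene KIF11 rose by 1.28 ± 0.20 and the cyclin gene CCNB1 by 0.86 ± 0.15. This list's call was lost without COP1 siRNA replicate 3 (adjusted p = 0.092), without control replicate 1 (adjusted p = 0.083), with array quality weights (adjusted p = 0.085) and with cyclic loess (adjusted p = 0.053), with a camera range of 0.0083 to 0.37 over all alternatives. Of 21 AP-1 and immediate early genes, 10 rose and 2 fell, or 13 and 2 adjusted over the list alone (mean 0.28; camera adjusted p = 0.033; adjusted p = 0.14 with an estimated correlation). FOSB, an AP-1 subunit, rose by 0.90 ± 0.11. This call was lost without COP1 siRNA replicate 1 (adjusted p = 0.085), without control replicate 2 (adjusted p = 0.052) and with no background correction (adjusted p = 0.061), with a camera range of 0.0092 to 0.14 over all alternatives.

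In all, 4469 genes changed in Huh7, 2362 higher and 2107 lower, and the groups did not overlap for 33.5% of the genes tested, where chance gives 10%. The count was 1302 when Huh7 was fitted alone, 2392 with array quality weights and 2860 at an adjusted p under 0.01, and all 1302 were among the 4469 with the same sign. In simulated arrays that kept each array's own spread, with 200 genes changed per line, 239 Huh7 calls were false, 61.6% of that simulation's calls, and the share of false calls among the 4469 was not measured.

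In HepG2, interferon response genes and the glutathione transferase genes GSTA1 and GSTA2 rose after COP1 siRNA, and DNA replication genes fell. UBD, a ubiquitin-like modifier, rose by 2.33 ± 0.23 on the log2 scale (adjusted p = 2.9e-08), GSTA2 and GSTA1 by 2.30 ± 0.15 and 2.18 ± 0.11, and SLC51A, a subunit of a bile acid transporter, by 2.07 ± 0.11. The fibrinogen gene FGA rose by 1.57 ± 0.16. NQO1, a quinone reductase, fell by 2.39 ± 0.11 (adjusted p = 2.9e-14), CANX by 2.55 ± 0.12 and SPP1, the secreted protein osteopontin, by 2.17 ± 0.11. Each of these was on one side of the controls on 4 of 4 arrays, which the rule for naming them required. NQO1 also fell by 2.32 in Huh7 (limma adjusted p = 6.5e-13) and lay at background on every Hep3B array.

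Of 28 G1/S and DNA replication genes, 10 fell in HepG2 and 18 did not pass the test, and 10 also fell adjusted over the list alone (mean -0.36; camera adjusted p = 1.6e-05; adjusted p = 0.047 with an estimated correlation). The replication factor gene MCM10 fell by 1.94 ± 0.11, the ribonucleotide reductase gene RRM2 by 1.26 ± 0.18 and the DNA polymerase gene POLA1 by 0.91 ± 0.13. Of 30 G2/M and mitosis genes, 11 fell, the same number adjusted over the list alone (mean -0.29; camera adjusted p = 0.0013; adjusted p = 0.23 with an estimated correlation). TOP2A, a topoisomerase, fell by 0.94 ± 0.18 and the kinetochore gene CENPF by 0.89 ± 0.16. Of 24 interferon response genes, 8 rose, the same number adjusted over the list alone (mean 0.41; camera adjusted p = 4.0e-05; adjusted p = 0.0021 with an estimated correlation). IFIT1, an RNA-binding antiviral protein, rose by 1.88 ± 0.12, TAP1, a peptide transporter of antigen presentation, by 1.00 ± 0.10 and the interferon signalling factor gene IRF9 by 0.96 ± 0.11. Of 26 hepatocyte markers, 4 rose and 2 fell, the same numbers adjusted over the list alone (mean 0.12; camera adjusted p = 0.47). In all, 2577 genes changed in HepG2, 1256 higher and 1321 lower, and 1539 changed at an adjusted p under 0.01. The groups did not overlap for 25.0% of the genes tested, where chance gives 2.86%.

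In Hep3B, CXCL8, ESM1 and LSM14A rose after COP1 siRNA, and MRPL18, STK40 and some DNA replication genes fell. LSM14A, an RNA-binding protein of P-bodies, rose by 2.00 ± 0.14 on the log2 scale (adjusted p = 2.6e-10), the proteoglycan gene ESM1 by 2.00 ± 0.12, the adhesion molecule gene ALCAM by 1.77 ± 0.17 and CXCL8 by 1.55 ± 0.14. The mitochondrial ribosomal protein gene MRPL18 fell by 2.13 ± 0.15, the kinase-like gene STK40 by 1.84 ± 0.14 and CANX by 1.70 ± 0.12, and ADAM19, a metalloprotease, fell by 1.67 ± 0.13. Each of these was on one side of the controls on 4 of 4 arrays, which the rule for naming them required. SAR1B, a GTPase of vesicle transport, rose by 1.94 ± 0.11 on its main probe and by 1.45 on a second probe (adjusted p = 8.7e-08), while another had a log2 fold change of -0.09 (adjusted p = 0.79).

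Of 28 G1/S and DNA replication genes, 5 fell and 1 rose in Hep3B, the same numbers adjusted over the list alone (mean -0.18; camera adjusted p = 0.018; adjusted p = 0.25 with an estimated correlation). MCM10 fell by 0.96 ± 0.11 and the chromatin assembly gene CHAF1B by 0.61 ± 0.12. Both also fell in Huh7, MCM10 by 0.73 ± 0.12 and CHAF1B by 0.46 ± 0.14 (limma adjusted p = 5.3e-05 and 0.013). Of 30 G2/M and mitosis genes, 8 rose and 2 fell, or 10 and 3 adjusted over the list alone (mean 0.17; camera adjusted p = 0.13), and KIF11 rose by 1.32 ± 0.17. Of 24 interferon response genes, 1 rose and 1 fell, the same numbers adjusted over the list alone (mean -0.04, median 0.0038; camera adjusted p = 0.71). The kinase gene EIF2AK2 rose by 0.78 ± 0.14. Of 26 hepatocyte markers, 0 changed by limma, and 0 had an unadjusted p under 0.05. Only 6 of the 26 were above background on every array of a group in both Hep3B and Huh7, and CEBPA, FOXA3 and VTN were above background on 0 Hep3B arrays, so for most of the list a change was not fully measurable. In all, 2264 genes changed in Hep3B, 1171 higher and 1093 lower, and the groups did not overlap for 28.3% of the genes tested, where chance gives 2.86%. The count was 3922 when Hep3B was fitted alone, 4431 with array quality weights and 1283 at an adjusted p under 0.01. The order of the lines by their number of changed genes thus turned around, from Huh7 highest with a shared spread to Hep3B highest when each line was fitted alone. The balance of rises and falls also turned in each line with cyclic loess, to 2169 higher and 2253 lower in Huh7, 1356 and 1231 in HepG2 and 1066 and 1159 in Hep3B, and HepG2 had 758 and 1068 with no background correction.

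Several lists fixed beforehand had no call in any of the 3 lines, although the growth arrest list in Hep3B and the ubiquitin ligase list in HepG2 gained one under some alternatives (camera adjusted p from 0.041 to 0.14 and from 0.033 to 0.55). Of 33 growth arrest and DNA damage targets, 10 rose and 4 fell in Huh7, 4 rose and 1 fell in HepG2, and 8 rose and 2 fell in Hep3B. Adjusted over the list alone these were 11 and 6, 4 and 1, and 10 and 3, and the camera adjusted p was 0.55, 0.17 and 0.077. GADD45A, a growth arrest gene, rose by 2.09 ± 0.11 in Huh7 and by 0.60 ± 0.10 in Hep3B and had a log2 fold change of 0.0005 in HepG2. GDF15, a stress-induced cytokine, fell by 2.00 ± 0.22 in Huh7. TRIAP1 rose by 0.64 ± 0.14 in HepG2. Of 29 apoptosis regulators, 9 rose and 4 fell in Huh7, 5 rose and 3 fell in HepG2 and 4 rose and 4 fell in Hep3B, with a camera adjusted p of 0.57, 0.33 and 0.98. Adjusted over the list alone these were 9 and 5, 10 and 4, and 4 and 5. FADD, the adaptor of death receptors, fell by 1.44 ± 0.15, 1.62 ± 0.13 and 1.67 ± 0.13 in Huh7, HepG2 and Hep3B. Of 18 NF-kB and acute phase genes, 4 rose and 7 fell in Huh7, 2 rose and 2 fell in HepG2 and 3 rose in Hep3B, with a camera adjusted p of 0.26, 0.89 and 0.35. Adjusted over the list alone these were 4 and 7, 3 and 3, and 3. In Huh7 the acute phase gene ORM1 fell by 2.53 ± 0.26 while TNFAIP3, an inhibitor of NF-kB signalling, rose by 1.70 ± 0.15. Among 18 genes of COP1 and related ubiquitin ligases, COP1 included, 1 rose and 3 fell in Huh7, 2 rose and 3 fell in HepG2 and 3 rose and 1 fell in Hep3B, with a camera adjusted p of 0.46, 0.38 and 0.64. Adjusted over the list alone these were 1 and 3, 2 and 4, and 3 and 1.

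**Figure D2:**
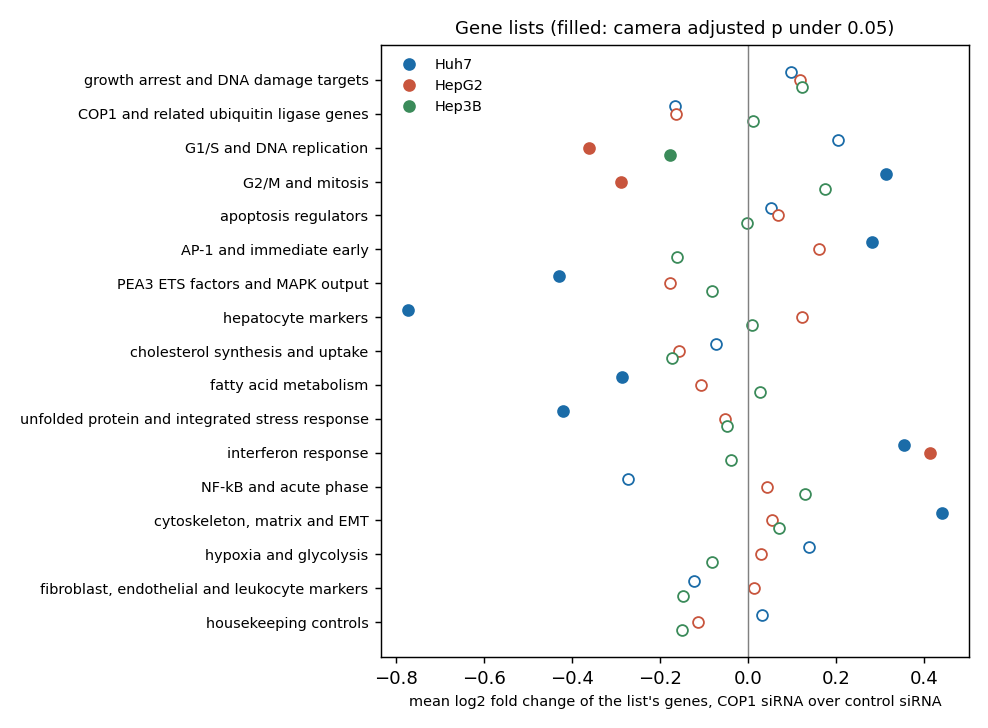
Mean log2 fold change (COP1 siRNA over control siRNA) of each of the 17 gene lists in the 3 cell lines; each circle is 1 list in 1 line, and filled circles have a camera adjusted p under 0.05. The hepatocyte markers in Huh7 have the lowest mean, -0.77.

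A further question was which genes changed in the same direction in all 3 lines. Among them were CANX, MRPL18 and the apoptosis adaptor gene FADD, all lower, and the histone gene H2AC6 and the zinc transporter gene SLC30A1, both higher. MRPL18 fell by 1.97 ± 0.18 in Huh7, 2.00 ± 0.15 in HepG2 and 2.13 ± 0.15 in Hep3B. SURF4, a cargo receptor of the secretory pathway, fell by 1.78 ± 0.11, 1.80 ± 0.09 and 1.33 ± 0.09, and COQ9 of coenzyme Q synthesis by 1.70 ± 0.12, 1.38 ± 0.11 and 1.42 ± 0.11. H2AC6 had log2 fold changes of 0.81 ± 0.20, 0.85 ± 0.17 and 0.78 ± 0.17, and SLC30A1 of 1.45 ± 0.16, 0.84 ± 0.14 and 0.55 ± 0.14. The size of the change still differed between lines for CANX, SURF4 and SLC30A1 (limma F test, adjusted p = 0.00042, 0.010 and 0.0065). ETV5, a PEA3 family member like ETV4, fell by 0.73 ± 0.13, 0.56 ± 0.11 and 0.45 ± 0.11, though its second probe did not pass in any line (adjusted p = 0.45, 0.50 and 0.080). In Huh7 the adjusted p of ETV5 was 0.058 when that line was fitted alone, the highest over all alternatives, of which the lowest gave 8.1e-07.

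In all, 294 genes changed in the same direction in all 3 lines, against 33.9 expected if the lines' calls were independent. Of these, 257 were lower, against 15.8 expected, and 37 were higher, against 18.1 expected. The expected numbers take all 13870 genes as equally able to be called. Of 4624 genes in the dimmest of 3 equal parts by mean level, 0 were higher and 2 lower in all 3 lines. The expected numbers, with those for pairs of lines below, are therefore likely too low, and the 37 may not exceed chance. At an adjusted p under 0.01, 170 genes were shared. Averaged over the 3 lines, 4360 genes changed, 2371 higher and 1989 lower, and 2859 changed at an adjusted p under 0.01. On this average the interferon response list rose (mean 0.24; camera adjusted p = 0.0011), with 11 of 24 members higher, also adjusted over the list alone. Its adjusted p was 0.0071 with an estimated correlation. The average also fell for the hepatocyte markers (12 of 26 lower and 2 higher; mean -0.21; camera adjusted p = 0.0052), the stress response list (12 of 26 lower and 1 higher; mean -0.17; camera adjusted p = 0.0056), the PEA3 list (6 of 16 lower and 1 higher; mean -0.23; camera adjusted p = 0.0056) and fatty acid metabolism (10 of 27 lower and 2 higher; mean -0.12; camera adjusted p = 0.049), and it rose for the EMT list (10 of 25 higher and 2 lower; mean 0.19; camera adjusted p = 0.014). These numbers were 12 and 2, 13 and 1, 6 and 2, 11 and 2, and 12 and 2 adjusted over the list alone, and with an estimated correlation the adjusted p was 0.016, 0.016, 0.045, 0.36 and 0.33. These 5 lists had a call in Huh7 and none in HepG2 or Hep3B, although the PEA3 list in HepG2 gained one under some alternatives (camera adjusted p from 0.032 to 0.23). The log2 fold changes of the lines correlated across genes with r = 0.418 for Huh7 and Hep3B, 0.135 for Huh7 and HepG2 and 0.049 for HepG2 and Hep3B (Spearman rho of 0.388, 0.033 and -0.063), where genes are not independent replicates. HepG2 and Hep3B had 376 genes lower in both, against 104 expected if independent, but 63 higher in both, against 106 expected.

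**Figure D3:**
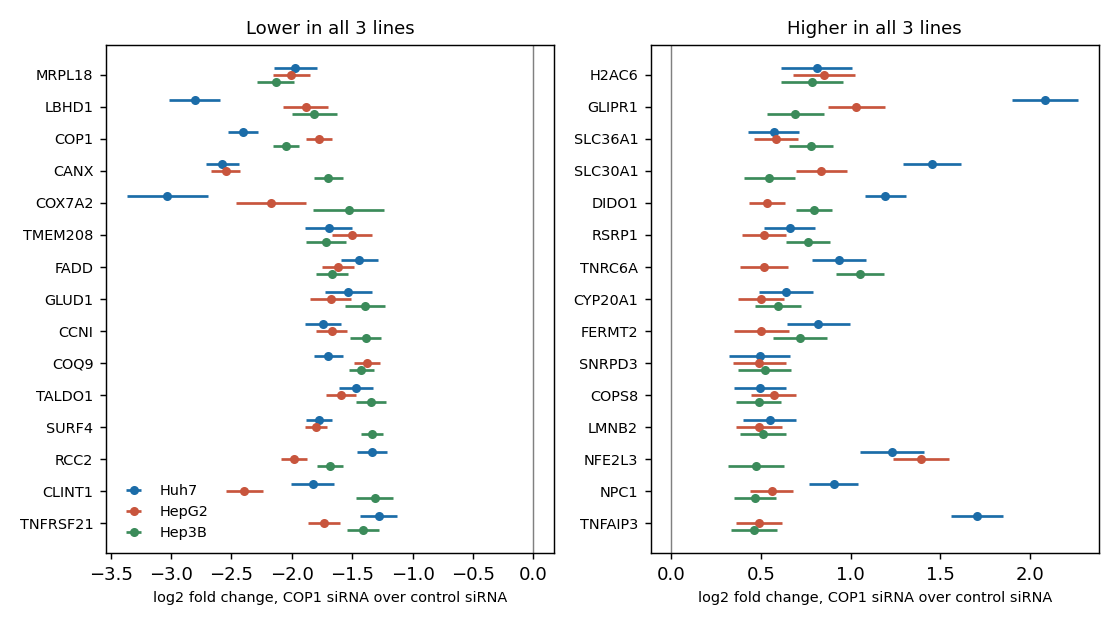
Log2 fold change (COP1 siRNA over control siRNA) of the 15 genes with the largest shared falls and the 15 with the largest shared rises; each point is 1 cell line, and the bars show the SE. Among the falls, FADD lies at -1.44, -1.62 and -1.67 in Huh7, HepG2 and Hep3B. Among the rises, the other probes of TNRC6A did not pass in any line (limma adjusted p from 0.076 to 0.86). Those of DIDO1 passed in HepG2 but not in Huh7 or Hep3B (limma adjusted p from 0.15 to 0.95).

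The last question was where the lines differed. CXCL16, a chemokine, fell by 2.33 ± 0.11 in Huh7, with log2 fold changes of 0.19 ± 0.10 in HepG2 and -0.11 ± 0.10 in Hep3B. SPP1 fell in HepG2 by 2.17 ± 0.11, and CXCL8 rose in Huh7 and Hep3B but fell by 0.63 ± 0.14 in HepG2. DDIT4, a stress-induced inhibitor of growth signalling, fell by 1.59 ± 0.18 in Huh7 and 1.41 ± 0.15 in Hep3B and rose by 0.85 ± 0.15 in HepG2. KIF11 and HSP90B1 rose in Huh7 and Hep3B and fell in HepG2, by 0.52 ± 0.17 and 0.95 ± 0.15. The adjusted p of the limma F test was 1.4e-11 for CXCL16, 1.6e-10 for SPP1, 5.5e-10 for CXCL8, 8.1e-09 for DDIT4, 2.5e-06 for KIF11 and 1.2e-06 for HSP90B1.

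Gene groups differed as well. The hepatocyte markers had a log2 fold change that was higher by a mean of 0.90 in HepG2 and 0.78 in Hep3B than in Huh7 (camera adjusted p = 2.8e-08 and 1.8e-08; adjusted p = 0.00028 for both with an estimated correlation). Many markers lay at background in Hep3B, CEBPA and FOXA3 among them, and the 6 of 26 above background in both Huh7 and Hep3B had a mean difference of 0.70 (camera adjusted p = 0.0031; adjusted p = 0.022 with an estimated correlation), a test added after seeing the data, with a camera range of 7.8e-12 to 0.0031 over all alternatives. The interferon response list's change was lower in Hep3B, by a mean difference of -0.39 from Huh7 and -0.45 from HepG2 (camera adjusted p = 0.0011 and 0.00058; adjusted p = 0.0086 and 0.0081 with an estimated correlation). That of the G1/S list was lower in HepG2 than in Huh7 by a mean difference of -0.57 (camera adjusted p = 1.9e-06; adjusted p = 0.021 with an estimated correlation). That of the G2/M list was lower in HepG2 than in Huh7 by -0.60 and higher in Hep3B than in HepG2 by 0.46 (camera adjusted p = 7.9e-05 and 0.00058; adjusted p = 0.12 and 0.21 with an estimated correlation). For the growth arrest list no difference between lines passed the test, with mean differences of 0.02 for HepG2 and 0.03 for Hep3B against Huh7 and 0.01 for Hep3B against HepG2 (camera adjusted p = 0.78, 0.80 and 0.84). In all, the response of 4735 genes differed between lines, 34.1% of those tested. The count was 3136 with no background correction and 2858 at an adjusted p under 0.01. Huh7 and HepG2 differed in 3617 genes, Huh7 and Hep3B in 2038 and HepG2 and Hep3B in 2744. Of the 13870 genes, 8801 were above background on every array of a group in both Huh7 and HepG2. This number was 8602 for Huh7 and Hep3B and 8642 for HepG2 and Hep3B. The other genes were counted too, and for these a difference may reflect a gene at background in 1 line. All of these counts rest on 1 spread shared by the lines. With each array's own spread, 61.6% of Huh7 calls were false in the simulated arrays, in which differences between lines were not scored. The share of false calls among these counts was thus not measured.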

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

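The test of whether an array carried the wrong siRNA label was chosen only after its result was seen, as were the normexp offset of 16, the floor at the background threshold and the list test on genes above background in both lines compared. The other tests were written down beforehand.

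Replicate 3 of the Huh7 COP1 siRNA group stood apart from replicates 1 and 2, with a root mean square deviation from the group mean of 0.418 against 0.274 and 0.218. RNA of another line is argued against, since genes of HepG2 and of Hep3B that Huh7 controls lack were not raised on this array (the higher of the medians was -0.037 on the log2 scale, over 41 genes of HepG2, and the other -0.048, over 77 genes of Hep3B). A control sample under the wrong label is argued against, since COP1 on this array lay -2.36 on the log2 scale from the lowest Huh7 control. Whether the array shows the same response at a larger size was tested by correlating, across genes, its deviation with the response of the remaining replicate. The 2 correlations were 0.162 and -0.016, with a mean of 0.073. This mean lay under the limit set beforehand for arguing against this cause, while the first correlation lay above it. The 2 correlations thus disagree, so the test could not decide and the cause stays open. A difference between cultures or transfections may also be the cause and was not tested, as the labels name neither.

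Many more genes fell than rose in all 3 lines, 257 against 37. The background step and scaling applied here are argued against as the cause, since the lowest ratio of falls to rises over 4 others was 6.68. Greater power among bright genes is argued against, since the ratio was 5.41 among genes of middle mean level and 8.15 among the brightest of 3 equal parts, with 2 falls and 0 rises in the dimmest. A shared consequence of COP1 loss, binding of the single siRNA to other transcripts and the authors' own normalization could each give this pattern and stay open, since a second COP1 siRNA, the siRNA sequence and values before normalization were not used here.

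Hepatocyte marker genes fell in Huh7, with a mean log2 fold change of -0.77. The array that stood apart is argued against as the whole cause, since the mean was -0.69 without it (camera adjusted p = 1.7e-09, and 2.5e-10 to 0.0018 over all camera alternatives). A fall of all bright genes is argued against, since the mean lay at the percentile 0.01, the lowest possible, among 10000 random lists matched on level. These values describe a fall of hepatocyte marker RNA in Huh7, found and tested on the same arrays, and do not give its cause. An effect of COP1 loss and an effect of the siRNA on other transcripts both stay open.

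Single arrays lay far from the others of their group for 12 of the named genes, in 13 of 282 groups of a gene. Chance gives such a case in about 1 in 20 groups, or 14.1 here. Only groups of 4 arrays were tested this way, so Huh7, with 3 arrays per siRNA, was left out. The values are log2 levels, with the range of the other 3 arrays beside each. In Hep3B after COP1 siRNA, replicate 4 had 9.93 for ADAM19 (9.49 to 9.54), 8.32 for CYB5R4 (8.80 to 8.86), 8.23 for H2AC6 (8.93 to 9.01), 11.01 for NFE2L3 (11.26 to 11.30) and 7.93 for RSRP1 (8.31 to 8.39). In Hep3B after control siRNA, replicate 2 had 13.05 for COX7A2 (12.75 to 12.79) and 9.92 for MCM10 (10.14 to 10.18). In HepG2 after COP1 siRNA, replicate 2 had 9.36 for HPRT1 (9.84 to 9.90), 11.85 for LMNB2 (12.13 to 12.18) and 7.87 for RRM2 (8.45 to 8.55). In the same group replicate 4 had 10.72 for NFE2L3 (10.45 to 10.47), replicate 3 had 11.48 for NPC1 (11.19 to 11.23) and replicate 1 had 8.46 for TNFAIP3 (8.66 to 8.69).

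For 99 of the 122 named genes the response to COP1 siRNA differed between the 3 lines (limma F test, adjusted p under 0.05). Over all 13870 genes tested the share was 34.1%. The named genes were picked partly by this F test and by large changes in single lines, so a high share among them was built in. The span, the highest minus the lowest log2 fold change of the 3 lines, is given for each of the 99. The change in a line where a gene lay at background was not fully measured, so such spans are uncertain. Each span is that of the gene's main probe. In HepG2, SEPTIN2 fell by 2.26 on it, while other probes had log2 fold changes of -0.12, -0.06 and -2.29 (limma adjusted p = 0.54, 0.81 and 6.4e-09). FXR1 fell by 2.04 in HepG2, while its other probes had 0.08 and -0.83 (limma adjusted p = 0.70 and 0.00013). The widest spans were 3.14 for STC2, 2.95 for GBP1, 2.87 for ORM1, 2.81 for SLC51B, 2.78 for CXCL8, 2.68 for INHBE, 2.67 for LSM14A, 2.59 for CD14, 2.52 for CXCL16, 2.49 for NUPR1, 2.47 for OLR1, 2.44 for DDIT4, 2.43 for FOXA3, 2.43 for PCDH7, 2.38 for GSTA2, 2.35 for NQO1, 2.31 for UBD and 2.30 for SPP1. Spans were 2.29 for SLC51A, 2.29 for GSTA1, 2.22 for ELOVL6, 2.20 for CEBPA, 2.16 for TAGLN, 2.14 for IFIT1, 2.09 for GADD45A, 2.08 for UNC93A, 2.08 for ANXA1, 2.03 for PTBP3, 2.03 for TOP1MT, 2.02 for CTDSPL, 2.02 for NAT8B, 2.02 for FGA and 2.01 for ETV4. Further spans were 1.98 for ESM1, 1.97 for SAR1B, 1.94 for LCP1, 1.89 for CIDEC, 1.85 for PHGDH, 1.84 for KIF11, 1.80 for SPOCK2, 1.77 for ALCAM, 1.74 for F3, 1.71 for CENPF, 1.70 for FGG, 1.70 for SLC2A1, 1.69 for HSP90B1, 1.68 for FADS1, 1.68 for ASGR1, 1.68 for SNRNP27, 1.68 for IPO11, 1.67 for ADAM19 and 1.67 for ELOVL3. Below these came spans of 1.63 for CYB5R4, 1.53 for GDF15, 1.51 for SEPTIN2, 1.502 for COX7A2, 1.48 for TOP2A, 1.43 for TAP1, 1.40 for TRIB3, 1.39 for GLIPR1, 1.34 for ASNS, 1.27 for RRM2, 1.26 for IRF9, 1.249 for IFIH1, 1.246 for CXCL10, 1.24 for TNFAIP3, 1.23 for CCN1 and 1.21 for MCM10. Others were 1.16 for MX1, 1.16 for CDH2, 1.12 for LYZ, 1.11 for FXR1, 1.11 for VIM, 1.10 for PFKFB3, 1.08 for CLINT1, 1.08 for MMGT1, 1.07 for PHLDA1, 1.02 for PRC1, 1.01 for FASN and 0.99 for LBHD1. The remaining spans were 0.97 for EIF2AK2, 0.97 for VTN, 0.96 for POLA1, 0.96 for STK40, 0.92 for NFE2L3, 0.90 for SLC30A1, 0.90 for SFN, 0.89 for CCNB1, 0.88 for CANX, 0.81 for FOSB, 0.74 for IFI35, 0.70 for RPUSD3, 0.66 for DIDO1, 0.65 for RCC2, 0.63 for COP1, 0.61 for UBE2Z, 0.59 for HPRT1, 0.47 for SURF4 and 0.39 for SPRY4.

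The change of 10 gene lists differed between lines in 17 comparisons (camera adjusted p under 0.05), given here as differences in mean log2 fold change. HepG2 minus Huh7 was 0.90 for hepatocyte markers, 0.37 for the unfolded protein and integrated stress response, -0.57 for G1/S and DNA replication, -0.60 for G2/M and mitosis and -0.39 for cytoskeleton, matrix and EMT. Hep3B minus Huh7 was 0.78 for hepatocyte markers, 0.37 for the unfolded protein and integrated stress response, 0.35 for PEA3 ETS factors and MAPK output, 0.31 for fatty acid metabolism, -0.38 for G1/S and DNA replication, -0.44 for AP-1 and immediate early genes, -0.39 for the interferon response, -0.37 for cytoskeleton, matrix and EMT and -0.22 for hypoxia and glycolysis. Hep3B minus HepG2 was 0.46 for G2/M and mitosis, -0.32 for AP-1 and immediate early genes and -0.45 for the interferon response. With an estimated correlation the adjusted p was over 0.05 for G2/M (0.12 and 0.21), EMT (0.41 and 0.33), hypoxia (0.22), fatty acid metabolism (0.28), PEA3 (0.059), the AP-1 difference between Hep3B and HepG2 (0.059), the G1/S difference between Hep3B and Huh7 (0.059) and the stress response difference between HepG2 and Huh7 (0.059). With only genes above background in both lines it was over 0.05 for EMT (0.19) and the stress response (0.087) in HepG2 minus Huh7 and for PEA3 (0.058) in Hep3B minus Huh7. The G1/S difference between Hep3B and HepG2, with no call here, had an adjusted p from 0.0056 to 0.39 over all camera alternatives.

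Whether chance could give such counts was tested by counting changed genes for other splits of the arrays. In Huh7 the real split gave 4469 genes and the highest of the others 365, and 10 splits are too few for a share under 0.05. In HepG2 the real split gave 2577 genes and the others at most 1, over 35 splits. In Hep3B these were 2264 and at most 1, also over 35. The share of splits with such a count was thus under 0.05, which argues against chance but does not exclude it. Splits that mix the siRNAs put the siRNA effect into the residual spread, which by itself lowers their counts. All splits take the arrays as independent, so a difference between cultures or batches was not tested. Over 100 draws, the real one included, the highest other count was 0 against the 294 shared genes. For the 4735 genes that differed between lines it was 44. Those draws mixed line labels and so spread the Huh7 COP1 siRNA arrays, which varied most, over all lines. They could not show how far the unequal spread adds to the 4735. For the 4360 genes changed on average the highest other was 2987, in draws that keep the true labels of some lines. In these drawn tests too the real count was the highest, a share under 0.05. For the 4360 genes this argues against chance but does not exclude it. For the 294 genes the draws cannot decide, since a shared gene must be called in every line. Splits that mixed the siRNAs gave at most 1 gene in HepG2 and in Hep3B, so a drawn count near 0 was almost fixed beforehand. For the 4735 genes the draws cannot decide either, since they mixed the unequal spread over the lines.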

How the results depend on the processing

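The normexp offset of 16, the floor at the background threshold and the list test on genes above background in both lines compared were chosen only after seeing the data. COP1 fell in all 3 lines under every alternative run. When each line was fitted alone, 1302 genes changed in Huh7 and 3922 in Hep3B, and with array quality weights 2392 and 4431. At an adjusted p under 0.01 the counts were 2860 in Huh7, 1539 in HepG2, 1283 in Hep3B, 170 shared, 2859 on average and 2858 differing between lines, by the stricter threshold. With no background correction 3136 differed between lines. Leaving out 1 array gave 3464 to 5264 genes in Huh7, 1975 to 3807 in HepG2, 1647 to 3334 in Hep3B, 248 to 403 shared and 4164 to 5822 differing between lines. Without Huh7 COP1 siRNA replicate 3, Huh7 had 4002 genes, 3201 of them among the 4469, and 278 of the 294 shared genes were kept. A block by replicate number gave 3756, 2054 and 1697 genes in Huh7, HepG2 and Hep3B. Arrays of the same number correlated from -0.28 to 0.10 across genes, and those of different numbers from -0.27 to 0.37. The numbers thus gave no sign of pairing samples, and a factor shared between the siRNA groups was not tested. Of 221 results of named genes, 12 calls were lost with no background correction, 9 when lines were fitted alone, 9 at an adjusted p under 0.01 and 0 with a trended, robust eBayes. Apart from the thresholds and sample numbers, the cause was not tested.

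The following values, in mean log2 fold change, had the opposite sign to those reported, and none was called. With no background correction these were apoptosis regulators in Huh7 (-0.0043) and Hep3B (0.13), other cell type markers in Huh7 (0.14), hypoxia in HepG2 (-0.17) and hepatocyte markers in Hep3B (-0.13). With cyclic loess they were the ubiquitin ligases (-0.0056) and hepatocyte markers (-0.0075) in Hep3B, the growth arrest list for Hep3B minus HepG2 (-0.019) and SPP1 in Huh7 (-0.041). With no filter it was other cell type markers in HepG2 (-4.2e-05). With a filter for every array of 1 group they were the growth arrest list for HepG2 minus Huh7 (-0.011) and Hep3B minus Huh7 (-0.0018). With every probe tested they were the ubiquitin ligases in Hep3B (-0.077) and the growth arrest list for Hep3B minus HepG2 (-0.024). With array weights they were housekeeping genes in Huh7 (-0.018), apoptosis regulators in Hep3B (0.0017) and SPP1 in Huh7 (-0.034). The offset of 16 gave apoptosis regulators in Hep3B (0.015), and the floor gave the same list (0.017), the growth arrest list (-0.030) and the interferon list (-0.040), both for HepG2 minus Huh7. With genes above background in both lines they were the growth arrest list for Hep3B minus Huh7 (-0.0094) and Hep3B minus HepG2 (-0.037). Leaving out 1 array gave -0.026 to 0.087 for housekeeping genes in Huh7, -0.011 to 0.0079 for apoptosis regulators and -0.0017 to 0.015 for hepatocyte markers in Hep3B, -0.018 to 0.11 for SLC51A in Hep3B and -0.080 to 0.11 for SPP1 in Huh7. For the growth arrest list it gave -0.0096 to 0.047 (HepG2 minus Huh7), -0.0040 to 0.052 (Hep3B minus Huh7) and -0.0086 to 0.024 (Hep3B minus HepG2).

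Background limits dim genes. The full neqc method, median scaling, quantile normalization within lines and a block by slide were not run, and the average and the difference between lines have no value when lines are fitted alone.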

Other observations

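No main test in this part was chosen after its result was seen. The ranges over all alternatives do include the offset of 16 and the floor, which were added after seeing the data. The lists of cholesterol synthesis and uptake, hypoxia and glycolysis, other cell type markers and housekeeping controls had no camera call in any line, although the cholesterol list in Hep3B gained one under some alternatives (camera adjusted p from 0.039 to 0.23). Of 16 cholesterol genes, 2 rose and 3 fell in Huh7, 4 fell in HepG2 and 3 fell in Hep3B, or 2 and 4, 4, and 3 adjusted over the list alone (camera adjusted p = 0.69, 0.27 and 0.077). LSS, the lanosterol synthase gene, fell by 0.79 ± 0.17 in Huh7, 0.56 ± 0.14 in HepG2 and 0.58 ± 0.14 in Hep3B, but its other probes did not pass in HepG2 (adjusted p = 0.13 and 0.84) or Hep3B (adjusted p = 0.64 for both), and 1 of the 2 passed in Huh7 (adjusted p = 0.029, and 0.060 for the other). Of 22 hypoxia and glycolysis genes, 9 rose and 3 fell in Huh7, 4 rose and 1 fell in HepG2 and 1 rose and 2 fell in Hep3B (camera adjusted p = 0.22, 0.82 and 0.27). Adjusted over the list alone these were 10 and 3, 7 and 2, and 1 and 4. The glucose transporter gene SLC2A1 rose by 1.02 ± 0.11 in Huh7 and fell by 0.68 ± 0.10 in Hep3B, and PFKFB3, a regulator of glycolysis, rose by 1.10 ± 0.11 in HepG2.

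Of 13 markers of fibroblasts, endothelium and leukocytes, 1 rose and 2 fell in Huh7, 1 rose and 2 fell in HepG2 and 2 fell in Hep3B (camera adjusted p = 0.88, 0.95 and 0.26). Adjusted over the list alone 2 fell in Huh7, 1 rose and 2 fell in HepG2 and 1 rose and 2 fell in Hep3B. The mean log2 fold change of this list in Huh7 was -0.12 and its median 0.11. CD14, a co-receptor that hepatocytes also express, fell by 2.08 ± 0.21 in Huh7. Of 10 housekeeping controls, 2 rose and 1 fell in Huh7, 1 rose and 2 fell in HepG2 and 1 fell in Hep3B, the same numbers adjusted over the list alone (camera adjusted p = 0.95, 0.69 and 0.13). HPRT1, of purine salvage, fell by 0.71 ± 0.15, 1.15 ± 0.13 and 0.57 ± 0.13 in Huh7, HepG2 and Hep3B, and its adjusted p in Huh7 was 0.061 when that line was fitted alone, the highest over all alternatives, of which the lowest gave 0.00016.

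Lists called in Huh7 gave these results in the other lines. Of the unfolded protein and integrated stress response genes, 3 rose and 3 fell in HepG2 and 3 rose and 1 fell in Hep3B, or 3 and 4, and 3 and 1 adjusted over the list alone (camera adjusted p = 0.53 and 0.82). Of the fatty acid metabolism genes, 4 rose and 6 fell in HepG2 and 3 rose and 2 fell in Hep3B, or 6 and 7, and 3 and 3 adjusted over the list alone (camera adjusted p = 0.54 and 0.95). The elongase gene ELOVL6 fell by 1.10 ± 0.17 in Huh7 and by 1.62 ± 0.15 in HepG2 and rose by 0.60 ± 0.15 in Hep3B. Of the PEA3 and MAPK output genes, 1 rose and 6 fell in HepG2 and 4 fell in Hep3B, or 1 and 6, and 1 and 5 adjusted over the list alone (camera adjusted p = 0.064 and 0.38, the former from 0.032 to 0.23 over all alternatives). The MAPK inhibitor gene SPRY4 fell by 0.72 ± 0.11, 0.70 ± 0.09 and 0.33 ± 0.09 in Huh7, HepG2 and Hep3B, and its adjusted p in Hep3B lay between 0.0014 and 0.053 over all alternatives, the highest with a block by replicate number. Of the AP-1 and immediate early genes, 4 rose and 1 fell in HepG2 and 3 fell in Hep3B, or 5 and 1, and 3 adjusted over the list alone (camera adjusted p = 0.13 and 0.063, the latter from 0.023 to 0.20 over all alternatives). Of the cytoskeleton, matrix and EMT genes, 3 rose and 2 fell in HepG2 and 3 rose in Hep3B, or 4 and 2, and 3 adjusted over the list alone (camera adjusted p = 0.58 and 0.44). Of the G1/S genes in Huh7, 8 rose and 2 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.077, and 0.025 to 0.37 over all alternatives).

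Fry tests a list against no change and not against other genes. The list results followed over the alternatives were those of each line and of some differences between lines. Of the results followed, fry called 23 that camera did not. Among these were rises of the growth arrest list in Huh7, HepG2 and Hep3B (adjusted p = 0.003, 0.00051 and 0.00046) and of the apoptosis regulators in Huh7 and HepG2 (adjusted p = 0.0024 and 0.00056), and falls of the ubiquitin ligase list, COP1 included, in Huh7 and HepG2 (adjusted p = 0.0021 and 0.0070). The 23 leave out the average and the other differences between lines, where fry called further lists that camera did not. On the average the growth arrest list was 1 of them (fry adjusted p = 1.2e-06, camera adjusted p = 0.067). Fry therefore did not set the growth arrest list apart from the others.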
